A study of Caenorhabditis elegans with 12 samples.

How the data were processed

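Small RNA was sequenced from whole hermaphrodites of N2, the standard wild-type strain of the nematode Caenorhabditis elegans, with a TruSeq small RNA library kit per the labels' protocols. The 12 libraries fall into 4 groups of 3 by age (day 5 or day 15) and by treatment. The treatments were 0.1% DMSO, the solvent, and 100 nM rotenone, an inhibitor of mitochondrial complex I, which was given for 24 hours from the L4 larval stage. The ages are those of the labels, which do not say whether the days count from hatching or from adulthood, so the time between the exposure and each age is not known. The groups and the lane tag of each library, L006 or L007, were taken from the labels. Lanes were balanced over treatment within each age and only partly over age: lane L006 held replicates 1 and 2 of both day 5 groups and replicate 1 of both day 15 groups. Replicate numbers follow the order of deposit and pair no samples. The labels do not say that the replicates were separate cultures, so every p-value measures the spread between these samples, which may be technical.

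The deposited values are whole-number counts of reads per microRNA hairpin, 1 column for each library, with no normalization. The submitters' processing notes name bcl2fastq 1.8.4, Trimmomatic 0.36, BWA 0.7.12-r1039 and SAMtools 1.3.1-9 without giving their order or role. The genome build, the hairpin reference, the counting rule and the treatment of reads that fit several hairpins are not given in the sources used here. The table has 250 rows named for precursors, so both arms of a hairpin are counted together, and a change of arm would not be seen. Counts of hairpins with near-identical copies are uncertain for that reason. The counts of mir-44 and mir-45 differed by at most 0.530% in any library and those of mir-5592-1 and mir-5592-2 by at most 8.27%, and each of these pairs was treated as 1 uncertain measurement in an alternative.

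Of the 250 hairpins, 238 had a read and 181 passed edgeR's filterByExpr with its minimum count of 10. The 69 untested hairpins held 0.00172% of the reads. Total counts ranged from 4215830 to 11045174 per library. A count of 3 corresponded to 0.272 to 0.712 CPM, which are counts scaled by library size. Pairs of libraries within a group differed by 28.3 to 419 times the chi-square per degree of freedom that sampling alone gives, so no library was taken for a copy of another, and their Spearman correlations were 0.989 to 0.993. By this measure pairs from 1 lane lay closer in day 5 DMSO (90.2, against 316 and 419 across lanes) and day 5 rotenone (28.3, against 177 and 249). The same held in day 15 DMSO (45.6, against 95.2 and 104). In day 15 rotenone the pair from 1 lane lay furthest apart (186, against 99.3 and 112). At day 15 the 2 libraries of lane L006, 1 of each treatment, differed least (34.2). The common biological coefficient of variation was 6.88%.

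Groups were compared with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test on counts scaled by TMM, in a model of 4 group means over all 12 libraries with 8 residual degrees of freedom. The comparisons were rotenone against DMSO at day 5 and at day 15, day 15 against day 5 in DMSO and in rotenone, the interaction of rotenone with age, and the average rotenone effect over both ages. A hairpin was called at a Benjamini-Hochberg adjusted p under 0.05 over the 181 hairpins of a comparison. The standard error (SE) of a log2 fold change was its size divided by the square root of F. CPM values of groups and libraries are scaled by TMM, so they differ somewhat from the share of a library's reads, while means over all 12 libraries, CPM minimums, percentages of reads and the CPM of a count of 3 are scaled by library size alone. All are relative and give no amount per worm. In simulated counts for the 181 hairpins, 20 draws each, the rotenone test at day 5 called 61.5% of hairpins changed 1.25-fold, 86.0% of those changed 1.5-fold and 94.3% of those changed 2-fold, with 1.20% of unchanged hairpins called. At day 15 these shares were 56.8%, 79.8%, 91.3% and 1.12%, and for ageing in DMSO 63.5%, 80.3%, 93.3% and 1.90%.

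Before the data were examined, 14 lists of hairpins were fixed: the let-7, miR-35, miR-51, miR-58, miR-63, miR-44, miR-72, miR-2, miR-50 and miR-238 families, the heterochronic hairpins, hairpins tied to lifespan and stress, mirtrons and tissue markers. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 between hairpins and Benjamini-Hochberg adjustment over the 14 lists. An estimated correlation and the fry test were the alternatives. The rule for named hairpins, fixed at the same time, takes up to 15 rises and 15 falls per comparison, ranked by size, among called hairpins with a mean of at least 10 CPM, the 5 lowest p-values where no hairpin was called, tested members of the lists, and the 5 most abundant hairpins.

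The alternatives fixed before the data were examined were RLE size factors, library size alone, DESeq2 1.42.0, limma-voom, no filter, a stricter filter of 50 CPM in 3 libraries, a lane term, leaving out the 3 most abundant hairpins, fitting only the groups compared, and leaving out each library in turn. Chosen after seeing the data were thinning the day 5 libraries to the mean day 15 total, leaving out mir-45 and mir-5592-2, and fitting each lane alone. Called list members and the hairpins named by size were followed through RLE size factors, library size alone, the lane term, DESeq2 and each left-out library. Coordinates and host genes were taken from the Ensembl 115 annotation of build WBcel235 by gene name for 246 of the 250 hairpins; let-7 was matched by the RefSeq gene at the same coordinates. Host genes were sought among protein-coding genes, and on the strand of the hairpin also among other genes apart from piRNA genes. Permutation tests over hairpins used 100000 resamples in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.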

Results

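Reads of microRNA hairpins were counted in 12 small RNA libraries of whole N2 worms, 3 for each combination of age and treatment. Total counts at day 5 ranged from 8845726 to 10481528 reads in DMSO and from 8891063 to 11045174 in rotenone. They were lower at day 15, from 4727531 to 5989717 in DMSO and from 4215830 to 5856949 in rotenone. The most abundant hairpin was mir-82 with a mean of 18.0% of the reads, followed by mir-72 with 9.11%, mir-58a with 7.27%, mir-57 with 5.65% and mir-80 with 5.39%. In a principal component analysis of log2 CPM the first component carried 83.3% of the variance and separated the ages, while the second and the third carried 3.58% and 2.64%.

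The first comparison asked how worms exposed to rotenone at the L4 stage differed from solvent controls at day 5. After rotenone, mir-71, a hairpin known to promote long life in worms, fell from 10874 ± 539 to 6725 ± 111 CPM (SD, n = 3), which is 1.62-fold (log2 -0.69 ± 0.06 SE; adjusted p = 2.6e-09, edgeR quasi-likelihood test). The developmental timing hairpins let-7 and mir-241 also fell, let-7 from 1914 ± 50.4 to 1491 ± 140 CPM and mir-241 from 224 ± 20.7 to 151 ± 14.4 CPM. Among the hairpins that rose were mir-1018 by 1.39-fold, mir-231 by 1.27-fold and mir-42, a member of the embryonic miR-35 family, by 1.22-fold. Of 181 hairpins, 46 were called, 11 higher and 35 lower, and 72 had an unadjusted p under 0.05.

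The falls of single hairpins were small. After mir-71 and mir-241 (log2 -0.57 ± 0.09, adjusted p = 2.65e-05 by edgeR's quasi-likelihood test), mir-77 fell by 0.50 on the log2 scale, from 7957 ± 231 to 5637 ± 9.68 CPM. The falls of mir-75 and mir-63 were -0.46 ± 0.08 and -0.39 ± 0.06 on the log2 scale. Falls between -0.36 and -0.33 were measured for let-7, mir-248, mir-70, mir-239a, mir-238, mir-48 and mir-249. The rises of mir-1829b and mir-250 were 0.29 ± 0.07 and 0.27 ± 0.06. In the WBcel235 annotation mir-71 lies in an intron of ppfr-1 on its strand (chromosome I, 9379927 to 9380020, minus strand), and mir-70 in an intron of pmp-5 (chromosome V, 6665536 to 6665635, minus strand). The hairpins mir-48 (chromosome V, 14364412 to 14364509) and mir-241 (14366188 to 14366283) are neighbours on the minus strand, outside protein-coding genes.

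All 6 heterochronic hairpins, which time larval development, fell: lin-4, mir-237, let-7, mir-48, mir-84 and mir-241 (6 adjusted over the list alone). The fall of mir-237 (log2 -0.30 ± 0.08) was no longer called without day 5 DMSO replicate 2 (-0.21, adjusted p = 0.0838 by edgeR's quasi-likelihood test) or with library size alone (adjusted p = 0.136), nor was that of let-7 with library size alone (adjusted p = 0.0710). The fall of lin-4 (-0.29 ± 0.09, adjusted p = 0.0193) ended without any 1 of 9 of the 12 libraries (-0.28 to -0.18, adjusted p = 0.0526 to 0.142), so 4 to 6 of the list were called with a library left out, and 2, mir-48 and mir-241, with library size alone. The list passed the camera test (adjusted p = 0.0037), with adjusted p = 0.285 with an estimated correlation. In the let-7 family, which shares let-7, mir-48, mir-84 and mir-241 with that list, 4 of 7 members fell (6 adjusted over the list alone) and mir-793, mir-794 and mir-795 had changes of -0.13, -0.20 and -0.18 (4 with any library left out and 2 with library size alone; camera adjusted p = 0.0037; adjusted p = 0.410 with an estimated correlation). Of 11 hairpins tied to lifespan and stress, 6 fell (7 adjusted over the list alone), among them mir-71, mir-239a and mir-238, and 0 rose (3 to 6 lower with a library left out; camera adjusted p = 0.0037; adjusted p = 0.213 with an estimated correlation). In the miR-63 family 4 of 5 members fell (4 adjusted over the list alone), with mir-65 at -0.30 ± 0.06 and mir-66 at -0.26 ± 0.06 (3 to 4 with a library left out and 2 with library size alone; camera adjusted p = 0.0037; adjusted p = 0.213 with an estimated correlation). With the 3 most abundant hairpins left out 3 heterochronic hairpins, 3 of the let-7 family, 3 tied to lifespan and stress and 1 of the miR-63 family fell.

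The miR-35 family, which is abundant in oocytes and embryos, was the list that moved upward (camera adjusted p = 0.0029; adjusted p = 0.213 with an estimated correlation). Of its 8 members 3 rose (4 adjusted over the list alone), namely mir-41 by 0.32 ± 0.09, mir-42 by 0.29 ± 0.07 and mir-39 by 0.21 ± 0.08, and the other 5 had values of 0.12 to 0.20. The call of mir-41 ended without day 5 rotenone replicate 3 (0.28, adjusted p = 0.0553 by edgeR's quasi-likelihood test), and that of mir-39 ended without any single day 5 library other than DMSO replicate 3 (0.17 to 0.22, adjusted p = 0.0761 to 0.179). With a library left out 1 to 5 members were called higher, with library size alone 6, and with the 3 most abundant hairpins left out 8. The family's share of hairpin reads was 8.70 ± 0.60% in DMSO and 10.4 ± 0.20% in rotenone (SD, n = 3). Among 7 tissue markers, mir-1 of muscle and mir-60 of intestine fell by 0.24 and 0.22 on the log2 scale (2 adjusted over the list alone). Their calls ended without any 1 of 10 libraries for mir-1 (adjusted p = 0.0549 to 0.307 by edgeR's quasi-likelihood test) and of 9 for mir-60 (0.0870 to 0.141). Both ended with library size alone, as with the 3 most abundant hairpins left out, where 0 markers fell and 1 rose. Neuronal lsy-6 and mir-124 had values of 0.17 ± 0.10 and 0.01 ± 0.12, and neither passed. The marker mir-791 had raw counts of 297, 278 and 199 in DMSO and of 253, 246 and 202 in rotenone, and did not pass. So lsy-6 and mir-124 do not show that neurons as a whole were unchanged. The tissue markers and the 8 other lists did not pass (camera adjusted p = 0.0722 to 0.813).

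The balance of rises and falls moved with the scaling and with the hairpins and libraries fitted. With TMM it was 19 higher and 22 lower with the stricter filter, and 21 and 25 with only the 2 groups compared. Without mir-45 and mir-5592-2 it was 18 higher and 24 lower. Leaving out 1 day 15 library, not part of this comparison, gave 15 to 19 higher and 24 to 26 lower. The called hairpins split into 17 higher and 29 lower with RLE size factors, 23 higher and 17 lower with library size alone, and 29 higher and 14 lower with the 3 most abundant hairpins left out, as the median change of all hairpins moved from -0.04 to 0.08. A scaling shifts all hairpins together, so places relative to that median barely move by construction and are no added support. Under these 4 scalings the heterochronic list lay at -0.28 to -0.27 from it and the miR-35 family at 0.22, and mir-71 lay at -0.65 with TMM. Of the 46 calls, 23 (10 higher and 13 lower) passed under 8 scalings, filters and tools, among them mir-71, mir-241, mir-77, mir-75, mir-63, mir-70, mir-238, mir-239a, mir-48, mir-248, mir-1018, mir-231, mir-42, mir-1829b and mir-250. Within lane L006, 42 of the 46 were called and 46 had the same sign. Within lane L007, with 1 library in each group compared, 45 had the same sign. The libraries of each lane are among those that selected the 46, so these counts are no independent support.

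**Figure D1:**
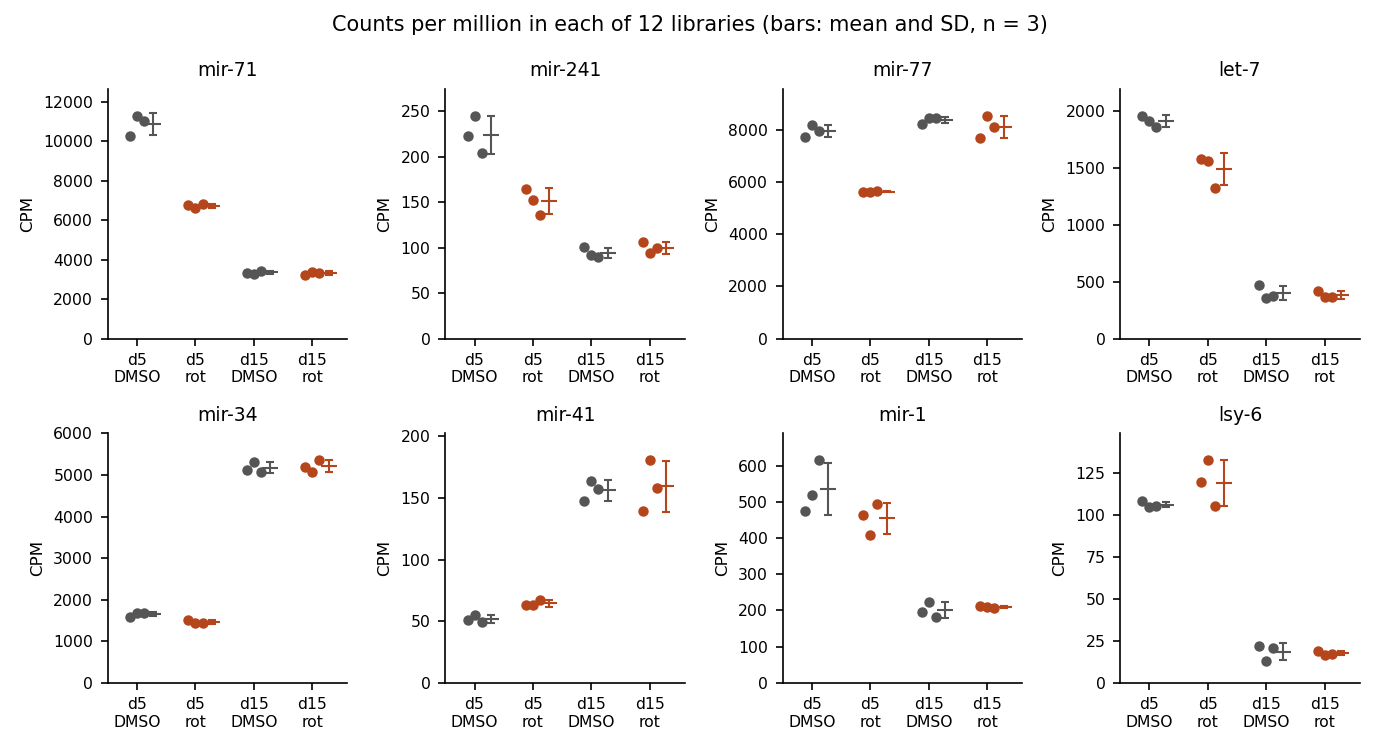
CPM of 8 hairpins in each library (dots), with mean and SD beside them (n = 3), at day 5 (d5) and day 15 (d15) in DMSO (grey) and after rotenone (rot, red-brown); every axis starts at 0. At day 5 the rotenone libraries lie below all DMSO libraries for mir-71, mir-241, mir-77 and let-7, and at day 15 the groups overlap for all 8 hairpins.

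At day 15, the comparison asked whether rotenone given at the L4 stage left a difference in day 15 worms. The hairpins that had differed at day 5 lay close together: mir-71 stood at 3355 ± 76.4 CPM in DMSO and 3316 ± 84.5 in rotenone (log2 -0.02 ± 0.06, 95% interval -0.14 to 0.11), and let-7 at 400 ± 64.2 and 382 ± 32.4 CPM (log2 -0.06 ± 0.09). For mir-241 the change was 0.08 ± 0.10, for mir-77 -0.05 ± 0.06 and for mir-1018 0.02 ± 0.08. No hairpin of 181 was called by edgeR's quasi-likelihood test: 0 calls, with 3 at an unadjusted p under 0.05, and 0 calls by DESeq2 and by limma-voom, with 2 and 3 at that level. The miR-35 family held 16.3 ± 0.68% of hairpin reads in DMSO and 16.6 ± 0.62% in rotenone.

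The 5 hairpins with the lowest p did not pass. For mir-234 the change was 0.52 ± 0.19, for mir-49 0.27 ± 0.13, for mir-5594 0.30 ± 0.18 and for mir-5593-2 -0.68 ± 0.39 (adjusted p = 0.918 for mir-234 and 0.968 for the others). For mir-4806 there were 12 reads over the rotenone libraries and 2 over the DMSO libraries, a ratio of 6.79 after scaling by library size with an exact 95% interval of 1.51 to 62.5 that covers counting error only (adjusted p = 0.882, edgeR quasi-likelihood test). None of the 14 lists passed (camera adjusted p = 0.587 to 0.991). Within lane L006, with 1 library per group and the spread pooled over groups, 3 hairpins were called, mir-49, mir-54 and mir-2209a; within lane L007 there were 0 calls with 3 at an unadjusted p under 0.05.

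The test of the difference between the ages was the interaction. The fall of mir-71 after rotenone was larger at day 5 than at day 15 by 0.68 ± 0.09 on the log2 scale (adjusted p = 5.02e-06, edgeR quasi-likelihood test), that of mir-241 by 0.65 ± 0.13 and that of mir-77 by 0.45 ± 0.09 (adjusted p = 0.00159 for both). The rises of mir-1018, mir-1829b and mir-250 at day 5 were likewise larger than their changes at day 15. In all, 12 hairpins were called, 9 with a positive and 3 with a negative difference, and 45 had an unadjusted p under 0.05. The calls were 4 positive and 4 negative without day 15 rotenone replicate 3, and 8 positive and 0 negative without day 5 rotenone replicate 2. All 12 were also called at day 5, and since the same day 5 libraries enter both tests the lists are not independent. The split was 4 positive and 7 negative with library size alone and 3 positive and 10 negative with the 3 most abundant hairpins left out; without day 5 DMSO replicate 3 there were 19 calls, with a lane term 29 (24 positive and 5 negative), and within lanes L006 and L007 there were 38 and 0.

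Of the lists, the heterochronic, let-7, lifespan and stress, miR-63 and miR-238 lists had positive and the miR-35 family negative differences (camera adjusted p = 0.0111 to 0.0498), and 0 lists passed with an estimated correlation. With a lane term the miR-238 family no longer passed (camera adjusted p = 0.0567). Across hairpins, which are not independent replicates, the rotenone changes at day 5 and day 15 had a Pearson correlation of 0.157 and a Spearman correlation of 0.126, and 90 of 181 had the same sign. Over both ages together, the average rotenone effect was called for 22 hairpins, 5 higher and 17 lower, with mir-71 at -0.36 ± 0.04, mir-77 at -0.27 ± 0.04 and mir-1018 at 0.25 ± 0.06. The largest called effect, a rise of 1.55, was that of mir-4806, which had a mean of 1.16 CPM. Its day 15 part rests on 12 reads in rotenone against 2 in DMSO and did not pass by itself. Of these 22, 21 were also day 5 calls. The number fell to 12 without day 15 DMSO replicate 1 (6 higher and 6 lower). It fell to 13 without DMSO replicate 3 (4 higher and 9 lower) or rotenone replicate 2 of that age (6 higher and 7 lower). There were 36 calls with a lane term. The split turned to 10 higher and 7 lower with library size alone and to 17 higher and 5 lower with the 3 most abundant hairpins left out, and within lanes L006 and L007 there were 32 calls (25 higher and 7 lower) and 0.

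**Figure D2:**
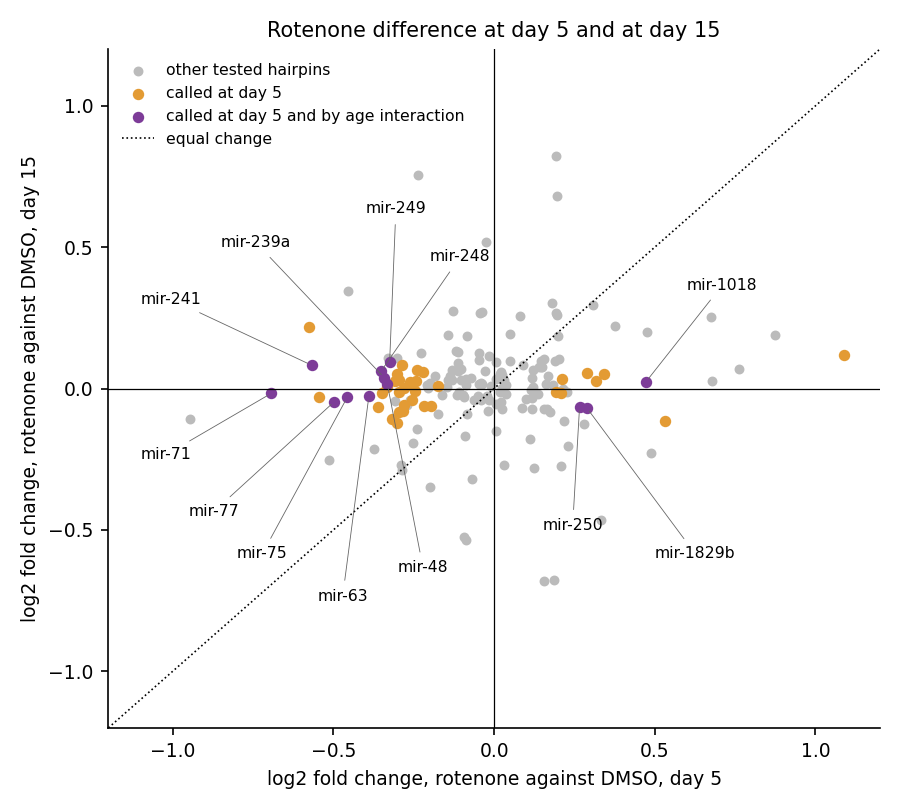
Log2 fold change of rotenone against DMSO at day 5 (horizontal) and day 15 (vertical) for 180 of 181 hairpins; 1 lies outside the axes. Coloured points are the 46 hairpins called at day 5, the 12 labelled ones also by the interaction, and they lie along the horizontal line at 0, off the dotted line of equal change.

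Ageing was compared first in the solvent controls. Between day 5 and day 15 in DMSO, mir-34, a hairpin of the stress response, rose 3.14-fold from 1648 ± 48.4 to 5175 ± 132 CPM (SD, n = 3; log2 1.65 ± 0.06, adjusted p = 9.77e-19, edgeR quasi-likelihood test). In the other direction let-7 fell 4.78-fold from 1914 ± 50.4 to 400 ± 64.2 CPM, mir-237 fell 4.22-fold, mir-71 fell 3.24-fold and the neuronal hairpin lsy-6 fell 5.72-fold from 106 ± 1.66 to 18.6 ± 4.83 CPM. All 8 members of the miR-35 family rose, led by mir-41 with 3.02-fold. Of 181 hairpins, 145 were called, 69 higher and 76 lower, and 66 of them changed by more than 1 on the log2 scale.

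Besides mir-34 and mir-41, the largest rises among hairpins with a mean of at least 10 CPM were those of mir-4807 (3.07 ± 0.17 on the log2 scale, at a mean of 16.0 CPM), mir-250 (1.53 ± 0.07), mir-786 (1.51 ± 0.10), mir-240 (1.36 ± 0.06) and mir-84 (1.28 ± 0.07). The hairpins mir-240 and mir-786 are neighbours on the plus strand of chromosome X (WBcel235, 7882622 to 7882718 and 7882751 to 7882840). Rises of 1.03 to 1.06 were measured for mir-239a, mir-246 and mir-795. Besides lsy-6, let-7, mir-237 and mir-71, the largest falls among these hairpins were those of mir-788 (-1.98 ± 0.18), mir-70 (-1.92 ± 0.08), mir-789-1 (-1.70 ± 0.15), mir-49 (-1.63 ± 0.12), mir-230 (-1.60 ± 0.09) and mir-253 (-1.55 ± 0.07). The let-7 locus is annotated on the minus strand of chromosome X (14743590 to 14745321), lsy-6 on the plus strand of chromosome V (10647232 to 10647304) and mir-34 on the minus strand of chromosome X (2969752 to 2969848).

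The miR-35 family was the list that passed the camera test (8 of 8 higher, 8 adjusted over the list alone; adjusted p = 0.0026; adjusted p = 0.453 with an estimated correlation). Its members rose by 0.48 to 1.60 on the log2 scale and its share of hairpin reads rose from 8.70% to 16.3%. Of these, mir-35 to mir-41 lie on the plus strand of chromosome II (mir-35 at 11537608 to 11537704 and mir-41 at 11538308 to 11538404), within Y62F5A.9, a gene on the other strand, and mir-42 lies apart from them (11889811 to 11889905). The let-7 family went both ways, with mir-84, mir-794 and mir-795 higher and let-7, mir-241 and mir-793 lower; its median was 0.08 and its mean -0.18. Of the heterochronic hairpins 4 fell and mir-84 rose (with library size alone 2 rose). Of the tissue markers 6 of 7 fell, which are lsy-6, mir-1 (-1.42 ± 0.09), mir-791 (-1.37 ± 0.15), mir-60 (-1.11 ± 0.07), mir-124 (-0.65 ± 0.13) and mir-228 (-0.23 ± 0.10), while mir-246 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.227). The call of mir-228 ended with RLE size factors, library size alone, DESeq2 or a lane term, and without any 1 of 4 libraries (adjusted p = 0.0644 to 0.279, edgeR quasi-likelihood test).

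Among the hairpins tied to lifespan and stress 5 rose, led by mir-34 and mir-239a, and 5 fell, led by mir-71 (5 and 5 adjusted over the list alone; camera adjusted p = 0.656). The count of falls was 3 with RLE size factors, library size alone or DESeq2, which ended the calls of mir-80 (-0.19 ± 0.08) and mir-228, and 3 to 5 with a library left out; the call of mir-80 ended without any 1 of 7 libraries (adjusted p = 0.0529 to 0.200, edgeR quasi-likelihood test). All 3 members of the miR-50 family fell and all 4 of the miR-44 family rose, as did 5 of 6 in the miR-51 family, 3 of 4 in the miR-2 family and 2 of 3 in the miR-238 family. Of the miR-44 family, mir-44 and mir-45 have near-identical counts and are 1 uncertain measurement. In the miR-58 family 4 of 5 tested members fell, with mir-58a at -0.55 ± 0.09, and with a library left out 1 to 4 fell; in the miR-44 family 2 to 4 then rose. In the miR-63 family 3 members fell and 1 rose (2 to 3 and 0 to 1 with a library left out), in the miR-72 family 1 fell and 1 rose, and of 3 tested mirtrons mir-62 and mir-1020 fell and mir-1018, which lies in an intron of the noncoding gene Y59E1B.1, rose. None of these lists passed the camera test (adjusted p = 0.227 to 0.848). By lane there were 140 calls in L006 and 115 in L007.

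The same comparison after early rotenone asked how ageing proceeded in exposed worms. Here mir-34 rose 3.57-fold from 1460 ± 45 to 5211 ± 148 CPM (SD, n = 3; log2 1.84 ± 0.06, adjusted p = 1.52e-19, edgeR quasi-likelihood test), and let-7 fell 3.90-fold from 1491 ± 140 to 382 ± 32.4 CPM. The fall of lsy-6 was 6.74-fold and that of mir-71 was -1.02 ± 0.06 on the log2 scale. All 8 members of the miR-35 family rose again, by 0.32 to 1.31 (7 within lane L007). Of 181 hairpins, 136 were called, 68 higher and 68 lower, and by lane there were 135 calls in L006 and 109 in L007.

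Other rises after rotenone were those of mir-4807 (2.80 ± 0.16), mir-786 (1.74 ± 0.10), mir-240 (1.60 ± 0.06), mir-84 (1.57 ± 0.07), mir-239a (1.44 ± 0.06), mir-795 (1.26 ± 0.08) and mir-85 (1.07 ± 0.09). Other falls were those of mir-788 (-2.28 ± 0.19), mir-237 (-1.90 ± 0.09), mir-70 (-1.59 ± 0.08), mir-244 (-1.42 ± 0.06), mir-4813 (-1.27 ± 0.08) and mir-791 (-1.27 ± 0.16). In the let-7 family mir-48 rose (0.43 ± 0.07) together with mir-84, mir-794 and mir-795, while let-7, mir-241 and mir-793 fell. The tissue markers split as in DMSO, 6 lower and mir-246 higher, and the call of mir-228 ended without day 5 rotenone replicate 2 (adjusted p = 0.0789, edgeR quasi-likelihood test). The miR-35 family was the list that passed the camera test (8 adjusted over the list alone; adjusted p = 0.0101; adjusted p = 0.357 with an estimated correlation).

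The age changes in DMSO and after rotenone come from different libraries, fitted in 1 model. Both carry the lower depth at day 15, the lanes only partly balanced over age, and any preparation that went with age. Their likeness therefore does not separate age from these. Of 181 hairpins 61 were higher with age in both treatments, where independent lists would share 25.9, and 64 were lower in both, where they would share 28.6. No hairpin (0 of 181) was called in opposite directions. Across hairpins, which are not independent replicates, the changes had a Pearson correlation of 0.949 and a Spearman correlation of 0.954. The differences between these age changes are the interaction values given above for mir-71, mir-241 and the other 10 hairpins.

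**Figure D3:**
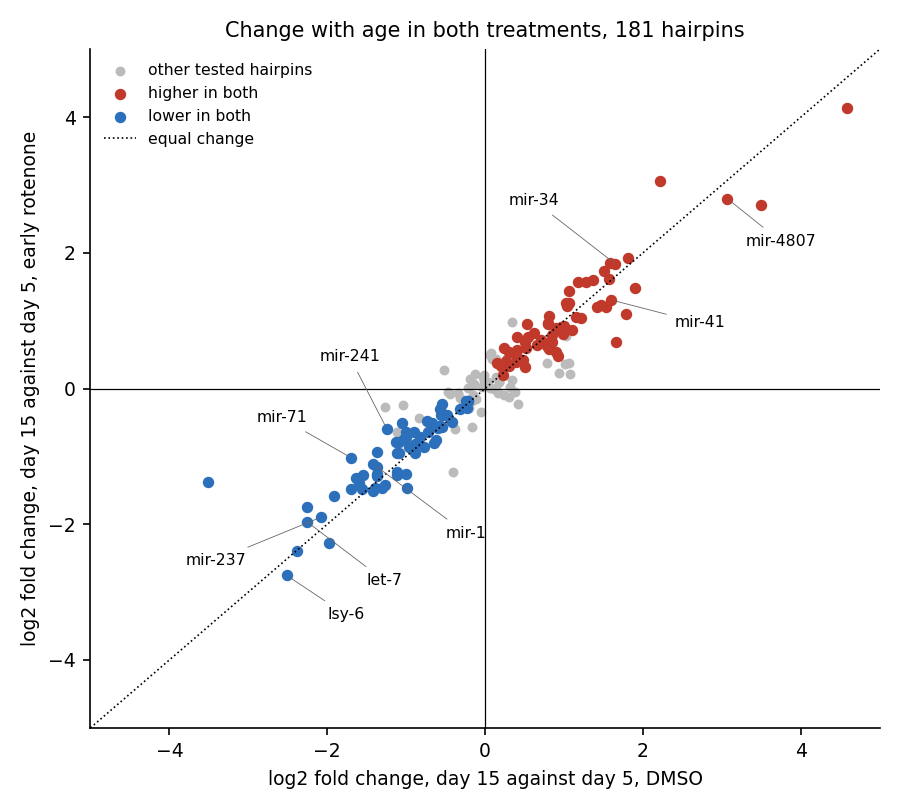
Log2 fold change between day 5 and day 15 in DMSO (horizontal) and after rotenone (vertical) for 181 hairpins; red points are the 61 higher in both, blue points the 64 lower in both, and the dotted line marks equal change. The rises of mir-34 and mir-41 and the falls of let-7, mir-237, mir-71 and lsy-6 are labelled, and mir-71 and mir-241 lie above the dotted line.

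**Figure D4:**
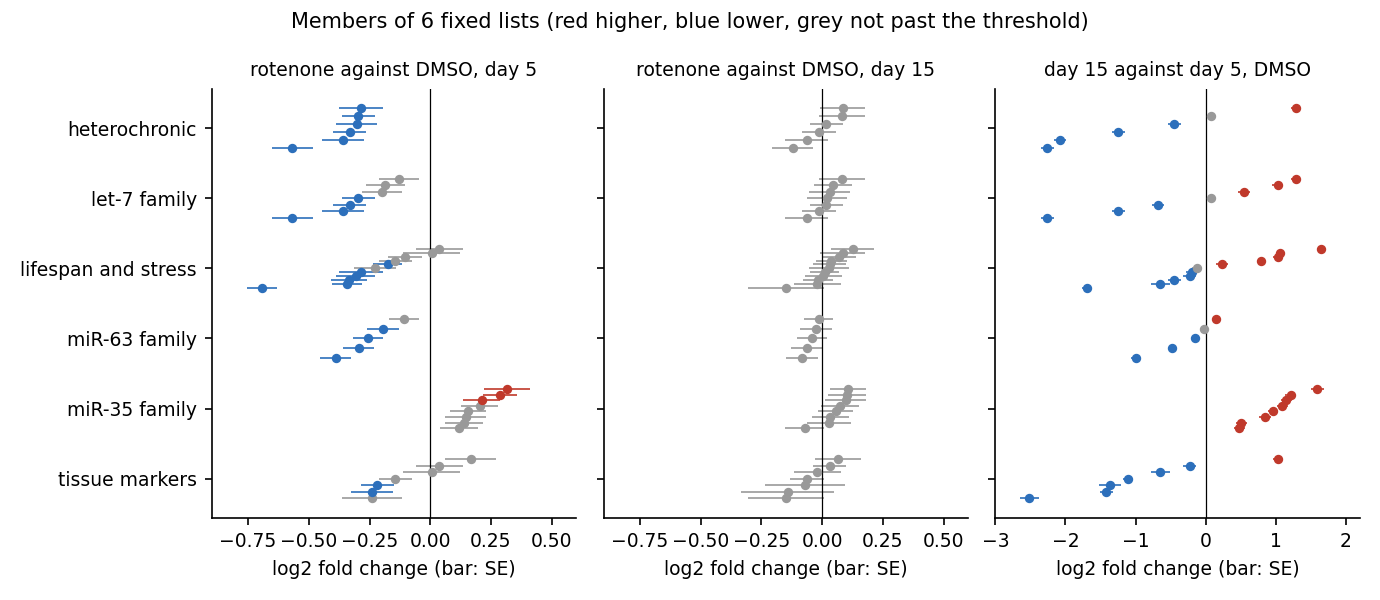
Log2 fold change with SE of the members of 6 fixed lists in 3 comparisons, coloured by call. At day 5 after rotenone all 6 heterochronic hairpins are lower, at day 15 none of the members is called, and with age all 8 miR-35 family members are higher; of the 6 heterochronic hairpins 4 to 6 are called with a library left out and 2 with library size alone in place of TMM.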

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

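The tests of scaling and of somatic markers and the thinning of the day 5 libraries were chosen only after the results or the data had been seen. The rotenone change differed between day 15 and day 5 by the interaction test (edgeR quasi-likelihood, Benjamini-Hochberg) for 12 hairpins. The differences, day 15 minus day 5 on the log2 scale, were 0.68 for mir-71 (adjusted p = 5.02e-06), 0.65 for mir-241 and 0.45 for mir-77 (both 0.00159), 0.43 for mir-75 (0.0188), 0.42 for mir-249, 0.41 for mir-248 and 0.36 for mir-63 (all 0.0152), 0.38 for mir-239a (0.00908) and 0.35 for mir-48 (0.0209). They were -0.45 for mir-1018 (0.0183), -0.36 for mir-1829b (0.0328) and -0.33 for mir-250 (0.0209). The calls of mir-71, mir-241, mir-77 and mir-239a held when any of the 12 libraries was left out.

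Without day 15 rotenone replicate 3, 5 of the calls ended (mir-75, mir-249, mir-248, mir-63 and mir-48; adjusted p = 0.0581 to 0.0783 by edgeR's quasi-likelihood test). Without day 15 DMSO replicate 3, 4 ended (mir-75, mir-248, mir-63 and mir-48; 0.0535 to 0.0634), and without DMSO replicate 1 of that age, 3 ended (mir-75, mir-249 and mir-248; 0.0555). Without day 5 rotenone replicate 2, 4 ended (mir-75, mir-1018, mir-1829b and mir-250; 0.0539 to 0.103), and without its replicate 1 the call of mir-1829b ended (0.0747). The call of mir-75 also ended without day 15 rotenone replicate 2 (0.0519). The call of mir-48 also ended without day 15 DMSO replicate 2 (0.108), day 15 rotenone replicate 1 (0.0517), day 5 DMSO replicate 2 (0.0548) or day 5 rotenone replicate 3 (0.0816). With library size alone the calls of mir-75 (0.0752), mir-249 (0.0507), mir-248 (0.0663), mir-63 (0.0752) and mir-48 (0.174) ended.

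The 46 calls at day 5 against 0 at day 15 were weighed against technical causes. Shallower day 15 libraries explain little of it: with the day 5 libraries thinned to the mean day 15 total 44 hairpins were still called. A lane difference, a separate cause, also explains little of the day 5 calls, as 57 were called with a lane term. Exchanged treatment labels at day 15 are argued against, since in the other 9 splits of the day 15 libraries the 46 hairpins moved in the day 5 direction by a median of at most 0.0322, against 0.299 at day 5. A difference present at day 5 and not detected at day 15 may be biological, a hypothesis found and tested on the same data. Loss of the most affected worms before day 15, other cultures at each age and the composition of the worm samples stay open, as none was tested.

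The predominance of falls at day 5, 35 of 46 calls, depended on the processing. With library size alone 57.5% of the calls were higher, and with TMM but only the 2 groups compared 45.7%. The relative order of the hairpins does not move with a scaling. The lower place of mir-71 and the heterochronic hairpins relative to the median, and the higher place of the miR-35 family, thus barely move by construction, which is no added support. The calls did move: with library size alone in place of TMM the heterochronic hairpins called lower went from 6 to 2. The miR-35 family members called higher went from 3 to 6. More germline or embryo RNA beside an unchanged soma would lower all somatic markers alike, and 6 of them (mir-1, mir-60, mir-124, lsy-6, mir-791 and mir-228) moved apart from -0.24 to 0.17, with a variance 3.23 times that given by their SE (95% point 2.21). Such a larger share with changes of single hairpins on top is not excluded by this spread. A partial change in some tissues stays open and was not tested.

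The rise of the miR-35 family with age, 8 of 8 members in both treatments, held under RLE size factors and library size alone (8 called in each treatment), after thinning (8 in DMSO) and with a lane term (8 in DMSO). The scalings could hardly end these calls. In DMSO they moved the median of all hairpins up, from -0.02 to 0.02 and 0.06. In rotenone library size alone moved it from 0.01 to -0.02, against a smallest member rise of 0.32 with TMM. With the 3 most abundant hairpins left out the smallest change, that of mir-37, was 0.22 ± 0.08, so a change in the share of these abundant hairpins is argued against as its whole cause. The 6 somatic markers fell unequally in DMSO, from -2.52 to -0.23, with a variance 44.95 times that given by their SE (95% point 2.21). This argues against an equal loss of all somatic RNA as the only change. Since 145 of 181 hairpins were called with age in DMSO, unequal falls were likely beforehand. A shared loss with other changes on top is not excluded. A larger share of oocyte or embryo RNA in the day 15 samples is a hypothesis that was not tested, and age, the design's own biological difference, was not tested apart from it.

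Regrouping the libraries gave the following. For rotenone at day 5 the real split of 6 libraries gave 46 calls and the highest of the others 0 (1 of 10 splits as large), and for day 15 the real split gave 0 and the highest other 1 (10 of 10). Ageing gave 145 calls in DMSO against at most 0 in the other splits (1 of 10), and 136 against 0 in rotenone (1 of 10). Each of the other splits puts libraries of both real groups together, so a real difference becomes spread within groups. For ageing, with its large difference, the absence of calls there was largely set in advance and is no added support. With 10 splits no share under 0.05 can be reached. For the interaction, 9 of 100 splits within each age gave 12 calls or more, with a highest other count of 27, and for the average effect 7 of 100 gave 22 or more, with a highest other count of 30, so by this count chance is not excluded. The 9 and the 7 include the real grouping, and the others among them left the day 5 groups as they are and regrouped only day 15 libraries. These keep the day 5 difference, so this count cannot decide on chance. For the interaction they gave 17 to 27 calls, more than the real grouping. Among the 91 splits that parted the day 5 groups, the highest count was 1 for both. Parting these groups likewise turns the day 5 difference into spread, so this low count is no added support.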

How the results depend on the processing

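The fits of each lane alone, with thinned libraries and without near-identical hairpins were chosen after seeing the data. Of 3376 values of named hairpins and called list members under other settings, 3121 kept their direction and their side of the threshold, 255 were no longer past it and 0 reversed; 209 of the 255 came from leaving out 1 library and 30 from library size alone, and the cause was not tested. Leaving out each library in turn gave 33 to 46 calls for rotenone at day 5, 0 to 0 at day 15, 130 to 146 for age in DMSO, 131 to 140 for age in rotenone, 8 to 19 for the interaction and 12 to 23 for the average effect; the cause was not tested. A lane term gave 29 interaction calls and 36 average calls. Libraries of 1 lane lay closer in both day 5 groups and in day 15 DMSO, and further apart in day 15 rotenone. Whether this is the cause was not tested. Lane L006 alone gave 3 calls at day 15 and 38 for the interaction, and lane L007 alone gave 1 at day 5, 0 for the interaction and 0 for the average effect, with 1 or 2 libraries per group, each lone library being assumed to vary like the others. The stricter filter gave 87 calls for age in DMSO and 87 in rotenone, with 102 hairpins tested in place of 181. With an estimated correlation 0 lists passed in any comparison, against 5 with the preset value for rotenone at day 5, 1 for age in each treatment, 6 for the interaction and 6 for the average effect; fry, which does not compare a list with other hairpins, passed 11 lists for age in DMSO and 12 in rotenone. No paired analysis was possible because the replicate numbers follow the order of deposit and pair no samples. Depth limits the rare hairpins: a count of 3 is 0.272 to 0.712 CPM, and mir-4806 rests on 2 reads in day 15 DMSO.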

Other observations

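The tests of hairpin neighbours and of the ageing direction among called hairpins were chosen only after values they measure had been seen; the tests of the X chromosome and of the ageing direction over all hairpins were set before. With age in DMSO some neighbouring hairpins moved together and others parted. On chromosome V mir-250 rose by 1.53 and its neighbour mir-61 by 0.81 on the log2 scale (WBcel235, mir-250 at 11769917 to 11770015 and mir-61 at 11770060 to 11770156, minus strand, outside protein-coding genes). On chromosome I mir-795 rose by 1.03 and mir-794, also of the let-7 family, by 0.55. Within the let-7 family on chromosome V mir-241 fell by 1.24 beside mir-48 at 0.08, which did not pass. On chromosome X mir-74 of the miR-72 family fell by 0.55 while mir-73 of that family was at 0.06, which did not pass, and their neighbour mir-75 rose by 0.53.

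A hypothesis is that hairpins chained on a strand, each starting within 5000 bases of the next, share a primary transcript and so change alike. There were 57 such hairpins in 20 places, and all 76 pairs within a place were compared. With age in DMSO their mean difference was 0.635 on the log2 scale, against 0.944 when the values were permuted among them (one-sided permutation test over hairpins, p = 0.00041, adjusted over 3 comparisons 0.000615). It was 0.631 against 0.843 with age in rotenone (permutation p = 0.00865, adjusted 0.00865) and 0.249 against 0.384 for rotenone at day 5 (p = 0.00039, adjusted 0.000615). Without the miR-35 family the difference in DMSO still passed (0.698 against 0.982, permutation p = 0.00518, adjusted 0.0155), while those with age in rotenone and for rotenone at day 5 did not (permutation, adjusted p = 0.0741 for both). Neighbours of one family have like sequences, and reads that fit several of them could give the same result. Without pairs of one listed family, which left 42 pairs, the difference in DMSO was 0.797 against 1.06 (permutation p = 0.0265, adjusted 0.0795). It was 0.809 against 0.990 with age in rotenone (permutation p = 0.109, adjusted 0.144) and 0.376 against 0.444 for rotenone at day 5 (p = 0.144, adjusted 0.144). Part of the likeness may thus come from shared reads. Like-named pairs outside the listed families, such as mir-2209a and mir-2209c, were kept, and hairpins within Y59E1B.1 gave many of the pairs.

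A larger share of early germline RNA at day 15 would lower X-linked hairpins, as the X chromosome is largely silent there; it is transcribed in late oocytes and embryos, on whose share the test does not bear. In DMSO the median change was 0.10 over 60 X-linked and -0.12 over 117 autosomal hairpins, the opposite direction (two-sided permutation test, p = 0.450, adjusted over 3 comparisons 0.450). With age in rotenone the medians were 0.18 and -0.06 (permutation p = 0.200, adjusted 0.300), and for rotenone at day 5 they were -0.09 and -0.03 (p = 0.190, adjusted 0.300). These p-values do not show that the groups of hairpins moved alike, so a larger early germline share is neither shown nor excluded, and the miR-35 family, on chromosome II, is not among the X-linked hairpins.

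A shift of the day 5 rotenone worms along the direction of ageing was tested with contrasts that are independent of each other, the rotenone change at day 5 and the change from the mean of both day 5 groups to day 15 DMSO. Across 181 hairpins Pearson's r was 0.176 and Spearman's rho 0.219, within the range of -0.324 to 0.347 of 100 simulations with no rotenone change. Among the 46 hairpins called at day 5, 29 had the same sign in both and Pearson's r was 0.473, above the range of -0.246 to 0.265 that the same simulations gave for these hairpins and within that of -0.570 to 0.587 for as many hairpins with the lowest p in each simulation. The fall of mir-71, let-7 and mir-237 and the rise of the miR-35 family go the way of ageing, while mir-239a and mir-84, which rose with age, were lower after rotenone (mir-84 not past the threshold with library size alone). A shift along the ageing direction is neither shown nor excluded by these values, since a correlation within a range of no change does not exclude a modest shift, and it stays open.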
